A study of Mus musculus with 6 samples.

How the data were processed

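RNA of GFP-positive spleen cells from mice with AML1-ETO9a leukaemia was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample, with 3 AES wildtype and 3 AES knockout samples. Per the labels, total RNA was extracted with RNeasy columns and labelled with biotin. The groups were taken from the sample labels. The labels do not state that the 3 samples of a group came from separate mice, so p-values measure the spread between these samples.

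The authors deposited a table of processed values that range from 2.67 to 14.4 and were used as log2 values. The log base, the background correction, the summary of probes and the normalization between arrays are not given in the sources used here, and the base was taken as 2 from the range and distribution of the values. Of 35512 rows, 1 had no value on any array and was left out. The platform annotation gave 1 gene symbol to 21789 rows, several symbols to 1621 and none to 12102. Only rows with 1 symbol were named and tested as genes. Of these, 21698 were matched by gene identifier to the GRCm38.p6 gene table, which also supplied chromosomes and RNA classes. The build behind the array annotation is not stated, and no coordinates are printed. Where a gene had several rows, which held for 999 genes, the row with the highest mean over all 6 arrays was used, which left 19938 genes. No detection calls were used, so values near the low end may be background, and small differences there are compressed.

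AES knockout was compared with wildtype with limma (lmFit and eBayes, two-sided, no block for replicate number, no filter on dim genes, no further normalization) and Benjamini-Hochberg adjustment over all genes at 0.05. A value of 1 gene was also compared with an exact permutation test. Gene lists were compared with camera (preset correlation 0.01, and an estimated one) and fry, adjusted over 37 lists. The lists covered ribonucleoproteins and ribosome production, the TLE family, signalling targets, haematopoietic lineages, other cell types of the spleen, cell cycle, stress, metabolism and sex-linked genes. Of 773 listed genes, 682 were measured under 1 symbol. Lists, designs, the rule for named genes and most alternatives were fixed before the data were examined. The classes of small nucleolar RNA, taken from the annotation, the chromosome medians and the Y-linked model term were chosen after the data were seen. That term marked knockout replicates 1 and 3, where Y-linked genes were low. Its genotype difference is therefore that of knockout replicate 2 alone from the 3 wildtype arrays.

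Genes were named by rule: Aes and its family; the 12 genes with the largest change in each direction among those past the threshold with groups that did not overlap, filled up by smallest unadjusted p where fewer passed, leaving out predicted and clone names; and up to 4 members of each described list by smallest unadjusted p. Other genes are named where a small count called them. Principal components used the 1000 most variable genes. Chromosome medians used genes with a mean log2 value above 8, and random lists matched on brightness were drawn 10000 times.

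Alternatives were quantile normalization, median centring, a filter on dim genes (above the array's median on at least 3 arrays), eBayes with trend and robust options, the replicate number as a block, the mean of all rows of a gene, each row tested on its own, array weights, a fold change of at least 2, a test without variance moderation, and leaving out each array in turn. An offset before the log was planned for linear values and was not run, since the values were already on a log scale. The 13722 rows with no or several symbols were tested apart, and 0 passed (550 at an unadjusted p under 0.05).

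The gene and list tests were tested on simulated data for the comparison of AES knockout with wildtype. These held 19938 genes, of which 200 were changed, with independent normal noise. Variances were those after eBayes moderation, which draws the variances of genes toward a common value. Of 100 genes changed 2-fold, 57% were recovered, and of 100 changed 4-fold, 87%, with 10 false calls among the unchanged genes. These shares hold only for data with that many changed genes, variances so moderated and independent noise. In the real data Aes, 4.34-fold lower, had a limma adjusted p of 0.234. A list of 30 genes shifted together was recovered and an unshifted one was not called. Members of real lists vary together, with an estimated correlation of 0.908 for neutrophil markers, so the simulation does not test the preset correlation. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.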

Results

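Gene expression was measured in mouse leukaemia cells with and without AES, a short member of the Groucho/TLE family of transcriptional co-repressors that lacks the WD40 domain of the longer members. Fetal liver cells from mid-gestation embryos that carried either wildtype or conditional Aes alleles were given AML1-ETO9a, a truncated form of the t(8;21) fusion protein that causes leukaemia in mice, and were transplanted. Tamoxifen was given 4 weeks later, and GFP-positive cells were sorted from the spleen. The 6 arrays, Affymetrix Mouse Gene 1.0 ST, comprised 3 AES wildtype and 3 AES knockout samples. Wildtype cells were collected when the mice died of leukaemia and knockout cells at the end of the experiment, so that genotype and time of collection differed together. The median log2 value of an array was 6.62, 6.55 and 6.56 in wildtype replicates 1 to 3 and 6.47, 6.51 and 6.65 in knockout replicates 1 to 3, and the number of arrays limits the precision of each comparison.

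The targeted gene was examined first. Aes, listed under its current symbol Tle5 and measured by probe set 10365136, had a mean of 11.11 ± 0.014 (SD, n = 3) in wildtype and 8.99 ± 0.29 (SD, n = 3) in knockout cells, a 4.34-fold lower level (log2 difference -2.12, SE 0.15). The values were 11.13, 11.10 and 11.11 on the wildtype arrays and 8.80, 9.33 and 8.86 on the knockout arrays, so that the groups did not overlap. The other family members Tle1, Tle2, Tle3, Tle4 and Tle6 had differences of -0.42, -0.13, 0.05, 0.06 and 0.08. Aes had the smallest p of the 19938 genes tested with limma, but its adjusted p was 0.234 and missed the threshold of 0.05, and an exact permutation test gave the smallest two-sided p that 3 against 3 allows, 0.1. Without knockout replicate 2 the adjusted p was 0.0372, the only one of the 15 alternatives under 0.05. The others, apart from the Y-linked term, ran from 0.141 to 1. Which exons are deleted and where the probes lie was not known, so residual signal is not a measure of residual protein.

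**Figure D1:**
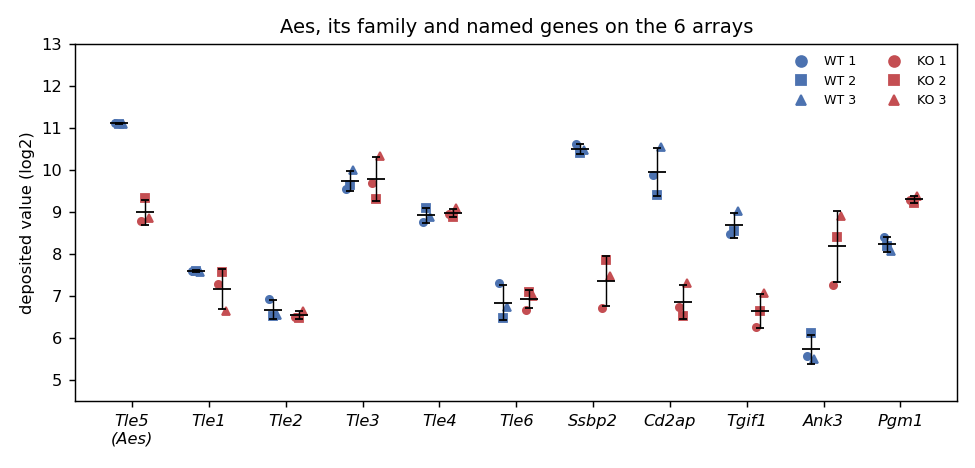
Deposited log2 values (y axis) of Aes (Tle5), the other TLE family members and 5 genes with small unadjusted p (x axis) on each wildtype (WT, blue) and knockout (KO, red) array, with the group mean and SD as black bars. Aes lies near 11.11 on the wildtype arrays and between 8.80 and 9.33 on the knockout arrays.

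No gene passed the threshold between AES knockout and wildtype cells. With limma, 0 of 19938 genes were higher and 0 were lower at an adjusted p of 0.05, and 505 had an unadjusted p under 0.05 (281 higher and 224 lower in knockout cells), where 997 are expected by chance. A test without variance moderation also called 0 genes, with 661 at an unadjusted p under 0.05. The groups did not overlap for 1426 genes, 7.15% of those tested, where chance gives 10%. The following genes have the smallest unadjusted p in each direction and did not pass the adjusted test. Ssbp2, which encodes a single-stranded DNA binding protein that partners LDB1, had a mean of 10.50 ± 0.11 (SD, n = 3) in wildtype and 7.36 ± 0.59 (SD, n = 3) in knockout cells, 8.81-fold lower (adjusted p = 0.505). Cd2ap, an adaptor between membrane receptors and actin, had means of 9.95 ± 0.57 and 6.87 ± 0.40 (SD, n = 3 each), 8.48-fold lower (adjusted p = 0.623). Tgif1, a homeobox co-repressor of TGF-beta signalling, had means of 8.69 ± 0.30 and 6.66 ± 0.40 (SD, n = 3 each), 4.09-fold lower (adjusted p = 0.874). Below these came Snora33, Rell1, Tifa, Rtl8c, Ndufa12, Snord104, Irak1bp1 and Snora62, with log2 differences between -1.58 and -0.55 and adjusted p of 1.00. In the other direction, Pgm1, a phosphoglucomutase, had means of 8.23 ± 0.17 and 9.30 ± 0.09 (SD, n = 3 each), 2.10-fold higher in knockout cells (adjusted p = 0.621). Ank3, the cytoskeletal adaptor ankyrin-G, had means of 5.74 ± 0.34 and 8.19 ± 0.84 (SD, n = 3 each, adjusted p = 1.00), and no fold is given because its wildtype values of 5.58, 6.13 and 5.51 lay below the array medians with no detection call. The lowest knockout values of Ssbp2 (6.71), Cd2ap (6.54) and Tgif1 (6.26) lay near or below the array medians with no detection call, so their folds depend on the background. Mst1r, Slc7a7, Ak1, Ei24, Mettl27, Ctps2, Stam2, Spata48, Purb and Hadhb had differences between 0.32 and 0.85, and the other probe set of Purb gave -0.009. For each of the 12 genes named per direction, the values of one group lay all above those of the other. Choosing genes by smallest p largely fixes this in advance.

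These counts of 0 changed without knockout replicate 2, where 3 genes were lower, Aes and the Y-linked Kdm5d and Uty. The Y-linked term, chosen after the data were seen, marked knockout replicates 1 and 3. It thus set knockout replicate 2 alone against the 3 wildtype arrays, and its counts are not given.

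Small nucleolar RNP components were a point of interest, since AES has been studied for a role in small nucleolar RNA formation in this leukaemia. One list held proteins of box C/D particles, which guide ribosomal RNA methylation, together with assembly factors and other associated proteins. Of its 13 measured genes, 12 had lower means in knockout cells, with a median difference of -0.10 and a camera adjusted p of 0.142. Nop58 and Nop56 had differences of -0.22 and -0.13, and the helicase Ddx21 of -0.13. A like list for box H/ACA particles, also with assembly factors, had 6 genes, of which 5 had lower means (median -0.11, adjusted p = 0.419). Among them were Nop10 at -0.21 and Nhp2 at -0.14. Ribosome biogenesis factors (43 measured, median -0.01, adjusted p = 0.414) and cytosolic ribosomal proteins (53 measured, median 0.006, adjusted p = 0.777) did not pass either. With quantile normalization, the box C/D list (median -0.13, adjusted p = 0.0247), ribosome biogenesis factors (-0.03, 0.0247) and ribosomal proteins (-0.008, 0.0328) passed as lower. Without knockout replicate 1, the box C/D list had a median of -0.23 (adjusted p = 0.00159) and ribosome biogenesis factors of -0.17 (0.000132). The latter also passed as lower without wildtype replicate 1 (-0.12, 0.0266) and as higher without knockout replicate 3 (0.10, 0.0377), where ribosomal proteins had -0.02 (0.0497). These calls rest on the preset correlation: with all arrays the estimated correlation was 0.721, 0.73 and 0.159 for the 3 lists and the adjusted p with it 0.991 for each. Non-coding host transcripts of small nucleolar RNAs fell as a list, with lower means for 5 of 5 measured members out of 18 listed, a median of -0.27 and an adjusted p of 0.0155. Snhg17 (-0.34) and Gas5 (-0.30) had the smallest unadjusted p among them. This call was lost with an estimated correlation (adjusted p = 0.48), and without wildtype replicate 2 (0.0637) or knockout replicate 1 (0.0549), and the median was -0.16 without knockout replicate 3. A wider set, chosen after the data were seen, of 27 genes, most of them protein-coding, that enclose 31 measured small nucleolar RNAs had a median of -0.0452 over those 31 RNAs. No member of these lists passed over all genes or adjusted over the list alone.

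The small nucleolar RNAs themselves were singled out as a class after their values had been seen. Of 53 measured small nucleolar RNAs, 48 had lower means in knockout cells, with a median difference of -0.36. Box C/D RNAs were lower for 26 of 30 (median -0.34) and box H/ACA RNAs for 20 of 20 (median -0.45). Snora33 had a mean of 9.07 in wildtype and 7.49 in knockout cells, Snord104 of 12.46 and 11.66, Snora73b of 11.43 and 10.36, and Snord85 of 6.71 and 6.02. The mean deviation of the class from its 6-array mean was 0.27, 0.40 and -0.004 on the wildtype arrays and -0.16, -0.16 and -0.35 on the knockout arrays. The camera p was 5.45e-28 with the preset correlation. Adjusted over these 3 overlapping classes alone, the p with an estimated correlation was 0.0403 for all small nucleolar RNAs, 0.0491 for box C/D and 0.0403 for box H/ACA RNAs. That of fry was 0.0411, 0.0517 and 0.0411, so that box C/D RNAs missed the threshold with fry. The fixed lists were adjusted over many more tests, so the classes cannot be said to pass where those lists failed. Unadjusted estimated-correlation p of 0.0374 for Notch targets and 0.0418 for non-coding hosts became 0.48 over the fixed lists. For all small nucleolar RNAs the unadjusted p was 0.0269, and it was not adjusted over those lists. Of the 53 RNAs, 26 had groups that did not overlap, where chance gives 10% for a single gene. These RNAs vary together (estimated correlation 0.284) and were singled out after their values had been seen. The count is therefore not one of independent members. The unadjusted estimated-correlation p was 0.0269 with all arrays and 0.0581 with array weights. It was 0.0839 without wildtype replicate 1, and 0.0885, 0.0521 and 0.0781 without knockout replicates 1 to 3. With the Y-linked term, which sets knockout replicate 2 alone against wildtype, the median was -0.30. Other short non-coding RNAs also had lower means, for 7 of 7 above a log2 value of 8 that are not themselves small nucleolar RNAs or the nucleolar RNAs Rmrp and Terc, with a median of -0.41. These included Rny3 (-0.68), Rpph1 (-0.44) and Rn7sk (-0.02), and Rpph1, Rprl1 and Rprl2 are all annotated as RNase P RNA. The dimmer ones went both ways. Vaultrc5 (-1.07), Rny1 (-0.47) and Rnu5g (-0.12) were lower, and Rnu6 (0.01) and Rnu7 (0.27) higher. No such cut on brightness was set for the small nucleolar RNAs.

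Of 37 gene lists, 13 passed camera with its preset correlation, 3 higher and 10 lower in knockout cells, and 0 passed with an estimated correlation or with fry. Interferon response genes fell as a list, with lower means for 27 of 28 measured members, a median of -0.58 and an adjusted p of 3.05e-09. Among them the chemokine Cxcl10 had means of 8.56 in wildtype and 6.18 in knockout cells, the transcription factor Irf9 of 9.91 and 9.43, and Gbp3 of 7.53 and 6.49. The adjusted p was 0.662 with an estimated correlation. With the Y-linked term, which sets knockout replicate 2 alone against wildtype, the median was -0.23. The median was -1.11 without wildtype replicate 1 and -0.31 without wildtype replicate 3. The list's mean deviation was 1.38 on wildtype replicate 3, against -0.39 and 0.24 on the other wildtype arrays and -0.96, 0.29 and -0.57 on the knockout arrays. Immediate early and heat shock genes fell as a list, with lower means for 16 of 20 members, a median of -0.37 and an adjusted p of 5.05e-05. Klf6 had means of 12.31 and 11.63, Dusp1 of 12.97 and 12.63 and Hspa1a of 9.15 and 6.98. The adjusted p was 0.781 with an estimated correlation and 0.0607 without wildtype replicate 1. The median was -0.14 without wildtype replicate 1, -0.70 without wildtype replicate 3 and -0.24 without knockout replicate 1. NF-kB and inflammatory genes had lower means for 18 of 21 members (median -0.25, adjusted p = 0.0075), with Ccl4 at -0.57 and Tnfaip3 at -1.06, while Tnf lay at 0.90. Their adjusted p was 0.781 with an estimated correlation, 0.76 without wildtype replicate 1 (median -0.07) and 0.437 without knockout replicate 1 (-0.12).

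Mitotic (G2/M) genes had lower means for 24 of 25 members, with a median of -0.20 and an adjusted p of 0.0018, for example Cenpf at -0.29, Ccnb2 at -0.26 and Mki67 at -0.20. The mean deviation was -0.67 on knockout replicate 3 and between -0.01 and 0.27 on the other 5 arrays. Without knockout replicate 3 the list turned higher (median 0.10, adjusted p = 0.0327), without knockout replicate 2 the median was -0.38, without wildtype replicate 1 the adjusted p was 0.0675, and with an estimated correlation it was 0.98. T cell markers had lower means for 14 of 18 members (median -0.11, adjusted p = 0.0111), with Cd8a at -0.22 and Cd3g at -0.72. Their adjusted p was 0.781 with an estimated correlation, and 0.276, 0.089 and 0.121 without wildtype replicate 1, wildtype replicate 2 or knockout replicate 1, and the median was -0.06 without wildtype replicate 1 and -0.19 without wildtype replicate 3. Notch targets had lower means for 9 of 12 members (median -0.12, adjusted p = 0.00763), with Dtx4 at -0.24 and Hes5 at -0.16. The adjusted p was 0.48 with an estimated correlation and 0.112 without wildtype replicate 1, and the median was -0.18 without knockout replicate 1. Genes of endoplasmic reticulum stress had lower means for 16 of 20 members (median -0.12, adjusted p = 0.0231), with the chaperone Hspa5 at -0.35 and Phgdh at -1.48, while Asns lay at 1.88. The adjusted p was 0.781 with an estimated correlation, and 0.513, 0.33 and 0.238 without wildtype replicate 1, wildtype replicate 2 or knockout replicate 1. The median was -0.07, -0.06 and -0.21 without wildtype replicates 1 to 3 and -0.08, -0.20 and -0.08 without knockout replicates 1 to 3. The TLE family list passed (median -0.04, adjusted p = 0.0235) through Aes itself: without Aes the adjusted p was 0.62, and with an estimated correlation 0.48. The adjusted p with Aes was 0.237 without wildtype replicate 1 and 0.167 without knockout replicate 1. The median of the family ranged from -0.17 to -0.02 with single arrays left out and was 0.05 with the filter on dim genes.

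Hypoxia and glycolysis genes rose as a list, with higher means in knockout cells for 19 of 23 members, a median of 0.25 and an adjusted p of 0.000117. Bnip3, a mitophagy receptor, had means of 8.43 in wildtype and 9.63 in knockout cells, the pyruvate dehydrogenase kinase Pdk1 of 8.62 and 9.31, and the glycolytic enzyme Pkm had a difference of 0.74. The adjusted p was 0.48 with an estimated correlation and 0.0685 without wildtype replicate 3, and the median was 0.17 without knockout replicate 2. Targets of p53 had higher means for 13 of 19 members (median 0.13, adjusted p = 0.0362). Ei24 had a difference of 0.46, Mdm2 of 0.28 and Rrm2b of 0.42, and Ei24 was the 1 member that passed adjusted over the list alone (0.0492). The list's adjusted p was 0.781 with an estimated correlation, and 0.948, 0.167 and 0.193 without wildtype replicate 3, knockout replicate 1 or knockout replicate 3. Its median was 0.21 and 0.24 without wildtype replicate 2 or knockout replicate 2, 0.05 without wildtype replicate 3 and 0.02 without knockout replicate 1, and -0.14 with the Y-linked term. B cell markers had higher means for 14 of 16 members (median 0.27, adjusted p = 0.0348), with Fcmr at 0.40 and Blk at 0.26, while Ighm lay at -1.18. Their adjusted p was 0.98 with an estimated correlation, and 0.729, 0.266 and 0.819 without wildtype replicate 3, knockout replicate 2 or knockout replicate 3. Their median was 0.48 without knockout replicate 1, 0.14 without wildtype replicate 3 and 0.026 without knockout replicate 3. Of the 13 lists, 2 passed with each array left out in turn, interferon response and the sex-linked genes. The sex-linked call was lost with array weights (median -1.57, adjusted p = 0.0894). The Y-linked term, built from 3 of the sex-linked genes, sets knockout replicate 2 alone against wildtype, so only its medians are given. They were -0.23 for interferon response, -0.0014 for sex-linked genes and -0.18 for non-coding hosts. For p53 targets, endoplasmic reticulum stress, Notch targets and T cell markers they were -0.14, -0.024, -0.17 and -0.16. G2/M genes turned higher there (median 0.17). With array weights the medians of G2/M genes (0.0068, adjusted p = 0.898), p53 targets (0.07, 0.169) and endoplasmic reticulum stress (-0.05, 0.285) moved toward 0 and their calls were lost. The calls of NF-kB genes (-0.23, 0.0664), T cell markers (-0.14, 0.0894) and the TLE family (-0.14, 0.0894) were lost there with a median close to or further from 0 than the -0.25, -0.11 and -0.04 above. The filter on dim genes ended the calls of B cell markers (0.020, 0.947) and T cell markers (-0.10, 0.368). Targets of p53 also missed the threshold with quantile normalization (0.10, 0.055), median centring (0.16, 0.0605), the trend and robust options (0.13, 0.0517) and the replicate block (0.13, 0.0587). Adjusted over the list alone, Aes and Ei24 were the only genes of the 37 lists to pass.

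**Figure D2:**
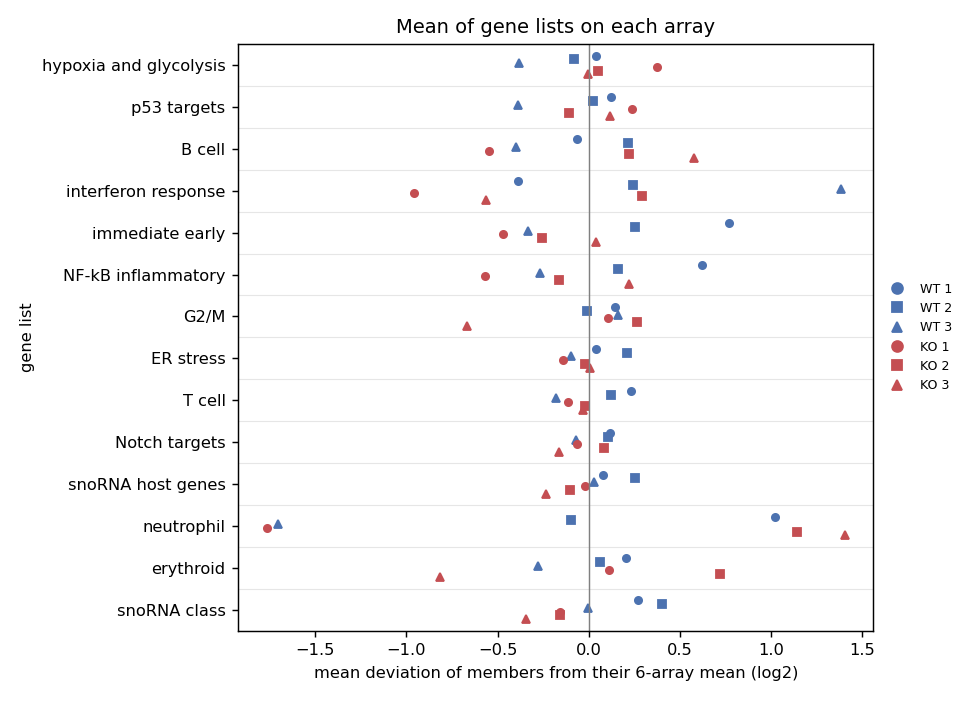
Mean deviation of the members of gene lists from their 6-array mean, in log2 units (x axis), for 14 lists (y axis) on each wildtype (WT, blue) and knockout (KO, red) array. Neutrophil markers lie between -1.76 and 1.40 with both groups spread over that range, and the small nucleolar RNA class lies at or above -0.004 on the wildtype arrays and at or below -0.16 on the knockout arrays.

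The other 24 lists did not pass. Neutrophil markers had higher means for 20 of 20 members (median 0.55, adjusted p = 0.063), with deviations of 1.02, -0.10 and -1.71 on the wildtype arrays and -1.76, 1.14 and 1.40 on the knockout arrays. They passed as higher with quantile normalization (adjusted p = 0.0489), the trend and robust options (0.0474) and array weights (8.62e-05). They also passed without wildtype replicate 1 (median 1.20, 6.56e-05) or knockout replicate 1 (1.47, 6.78e-11). With the Y-linked term, which sets knockout replicate 2 alone against wildtype, their median was 1.33. Their adjusted p was 0.991 with an estimated correlation, which was 0.908, and the median was -0.15 without wildtype replicate 3, 0.11 without knockout replicate 2 and -0.011 without knockout replicate 3. Of the 24 lists, 15 passed with at least 1 array left out, all by the preset correlation, and with all arrays their adjusted p with an estimated correlation lay between 0.781 and 0.991. Without wildtype replicate 1, primary granule genes (median 0.37) and cell cycle inhibitors (0.13) passed as higher. Without wildtype replicate 3, monocyte (-0.37), MHC class II (-0.52), NK cell (-0.11) and megakaryocyte markers (-0.12) passed as lower, as did monocyte (-0.54) and plasma cell markers (-0.35) without knockout replicate 3 and NK cell markers (-0.09) without knockout replicate 2. Erythroid genes passed as higher without knockout replicate 3 (0.28) and with array weights (0.16), and as lower without knockout replicate 2 (-0.23). G1/S genes passed as lower with quantile normalization (-0.10) and without knockout replicate 1 (-0.19) or 2 (-0.20). They passed as higher without knockout replicate 3 (0.17). With the Y-linked term the medians of erythroid and G1/S genes were 0.42 and 0.16. MYC targets passed as lower with quantile normalization (-0.11), with the replicate block (-0.08) and without knockout replicate 1 (-0.17) or 2 (-0.11), and oxidative phosphorylation with quantile normalization (-0.05) and without knockout replicate 1 (-0.08). Primary granule genes (median 0.07), monocyte and macrophage markers (-0.02), MHC class II and dendritic markers (-0.28), plasma cell markers (0.005), NK cell markers (-0.06), mast cell, basophil and eosinophil markers (-0.008), megakaryocyte and platelet markers (-0.11), erythroid genes (0.02) and stromal and endothelial markers (-0.01) had adjusted p of 0.981, 0.53, 0.226, 0.414, 0.102, 0.991, 0.226, 0.991 and 0.965. Stem and progenitor genes (median 0.03), genes associated with AML1-ETO (0.009), lineage transcription factors (0.04), Wnt targets (-0.02), MYC targets (-0.08), G1/S genes (-0.07), cell cycle inhibitors (0.04), oxidative phosphorylation (-0.02), BCL2 family and apoptosis genes (0.05) and adhesion genes (0.03) had adjusted p of 0.991, 0.991, 0.991, 0.407, 0.124, 0.198, 0.292, 0.767, 0.981 and 0.991. The median and the direction of the test had opposite signs for cytosolic ribosomal proteins, genes associated with AML1-ETO and plasma cell markers. The mean and the median had opposite signs for cytosolic ribosomal proteins, plasma cell markers, stromal markers, apoptosis genes and adhesion genes.

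The arrays did not separate by genotype. Pearson's r over all probe sets, which are not independent replicates, averaged 0.973 over the 6 pairs within groups and 0.975 over the 9 pairs between groups. The first principal component of the 1000 most variable genes held 32.1% of their variance and the second 24.5%, and wildtype and knockout arrays overlapped on both. Sex-linked genes passed as a list (median -2.86, adjusted p = 0.000415, and 0.48 with an estimated correlation), and their median was -4.29 without knockout replicate 2. The mean log2 value of the Y-linked genes Eif2s3y, Kdm5d and Uty was 9.23, 9.33 and 9.49 on the wildtype arrays and 9.36 on knockout replicate 2, but 4.46 on knockout replicate 1 and 5.16 on knockout replicate 3. Xist, transcribed from the inactive X chromosome, had values of 9.11, 7.41 and 5.08 on the wildtype arrays and 4.88, 5.84 and 5.66 on the knockout arrays.

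Genes of chromosome 12, assigned with the GRCm38.p6 annotation, varied together between arrays. For its 271 genes with a mean log2 value above 8, the median deviation from the 6-array mean was -0.32, -0.21 and 0.15 on the wildtype arrays and 0.52, -0.21 and 0.14 on the knockout arrays. The medians of the 19 other chromosomes, X included, lay between -0.07 and 0.09 on all 6 arrays. With dimmer genes included, the chromosome 12 medians were -0.11, -0.07 and 0.07 on the wildtype arrays and 0.18, -0.10 and -0.0011 on the knockout arrays, and with median centring that of knockout replicate 3 was 0.046. On knockout replicate 1, 94.5% of the chromosome 12 genes lay above their mean.

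**Figure D3:**
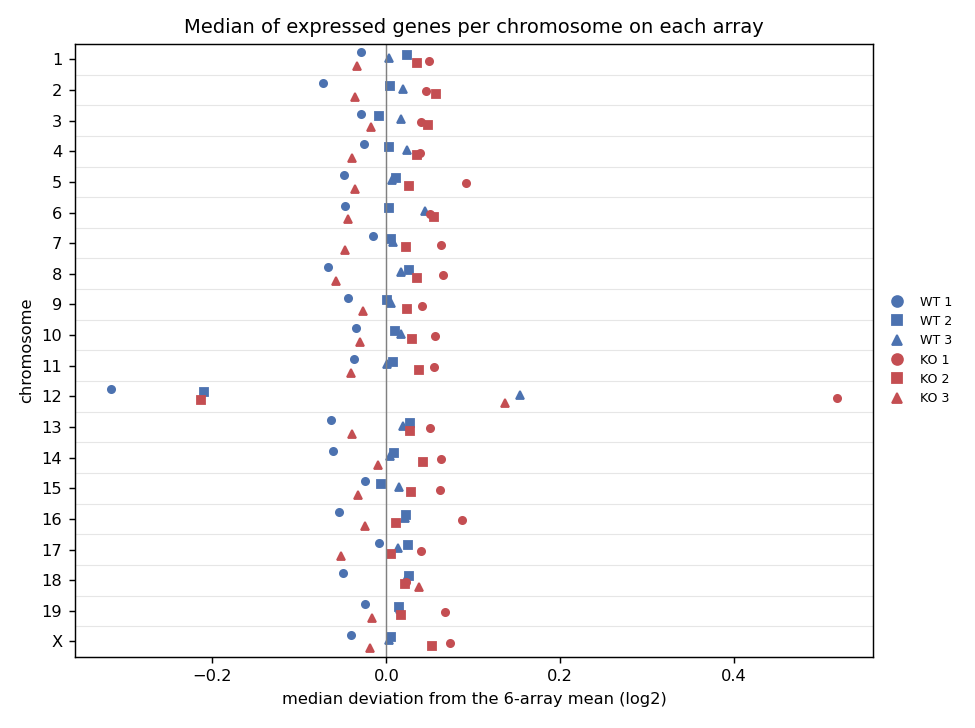
Median deviation of genes with a mean log2 value above 8 from their 6-array mean, in log2 units (x axis), for each chromosome (y axis) on each wildtype (WT, blue) and knockout (KO, red) array. Chromosome 12 ranges from -0.32 on wildtype replicate 1 to 0.52 on knockout replicate 1, while the other chromosomes lie between -0.07 and 0.09.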

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

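The Y-linked term, leaving out chromosome 12 genes, the TLE list without Aes, and all settings for small nucleolar RNAs and chromosome 12 were chosen after the data were seen. Explanations were examined only for the small nucleolar RNAs, the Y-linked genes and the chromosome 12 genes, as given below. No cause was established for any change. Leaving out single arrays gave 0 genes higher and 0 to 3 lower. The counts of 0 higher and 0 lower held under the other settings. The exception is the Y-linked term, whose counts are not given because it left 1 knockout array in the genotype difference. The difference of Aes lay between -2.29 and -2.02 with single arrays left out, with an adjusted p of 0.0372 without knockout replicate 2 and up to 1 otherwise. In 416 alternatives for 28 other named genes, 0 passed the threshold. The number of lists past the threshold, 13, was 19 with quantile normalization and 8 with array weights. It was 0 with an estimated correlation, 0 with fry, and 10 to 17 with single arrays left out. The median of small nucleolar RNAs lay between -0.46 and -0.27 with single arrays left out and kept its direction and its preset-correlation call under all settings. Its estimated-correlation p, unadjusted and for a class chosen after the data were seen, stayed under 0.05 in 9 alternatives. It did not in 6, namely array weights (0.0581), the Y-linked term, which rests on knockout replicate 2 alone, and without wildtype replicate 1 or any 1 knockout array.

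The direction of some lists turned. G2/M genes had a median of 0.0068 with array weights, 0.17 with the Y-linked term and -0.38 to 0.10 with single arrays left out. G1/S genes had 0.16 with the Y-linked term and -0.20 to 0.17 with single arrays left out. B cell markers turned in the test with the dim filter (median 0.020) and ranged from 0.026 to 0.48 with single arrays left out, erythroid genes from -0.23 to 0.28 and ribosome biogenesis from -0.17 to 0.10. Of 24 alternatives for the chromosome 12 medians, 14 stayed within the main interval, 9 moved beyond it and 1 turned. Including dim genes brought all 6 medians nearer to 0, with -0.0011 on knockout replicate 3, and median centring moved 4, to -0.38 on wildtype replicate 1 and 0.60, -0.16 and 0.046 on the knockout arrays. With the replicate number as a block, 0 genes were higher and 0 lower, 13 lists passed, and the adjusted p of Aes was 1. The series gave no statement of pairing, so the numbers were not taken to pair the samples. Deviations of same-numbered arrays from their group means correlated at -0.259, -0.228 and 0.0746 across genes. Those of wildtype replicate 1 and knockout replicate 2 correlated at 0.343, so these values do not settle whether samples were paired. Signal over background limits genes near the low end of the scale, where no detection call was used.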

Other observations

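The tests of the splits of the arrays and of brightness for small nucleolar RNAs were written before their results were seen, and the other tests here were chosen after. Erythroid genes, mast cell, basophil and eosinophil markers and megakaryocyte markers did not pass as lists, and their members with the smallest unadjusted p had the following values. The water channel Aqp1 had a mean of 10.27 ± 0.84 in wildtype and 8.40 ± 1.30 in knockout cells (SD, n = 3 each, adjusted p = 1.00), and it was the 1 of 21 measured erythroid genes whose groups did not overlap, where chance gives 10%. Epb42, a protein of the red cell membrane, had 7.80 ± 1.41 and 9.55 ± 1.52, and the blood group genes Ermap and Kel had differences of 0.15 and -0.12. Fcer1a, a subunit of the IgE receptor, had 11.39 ± 0.95 and 9.42 ± 1.75 (SD, n = 3 each), and the cytokine receptor subunit Csf2rb a difference of 0.32. The platelet genes Vwf and Ppbp had differences of -0.45 and -0.45. Erythroid genes deviated by 0.20, 0.06 and -0.28 on the wildtype arrays and 0.11, 0.72 and -0.81 on the knockout arrays, and mast cell, basophil and eosinophil markers by 0.97, -0.83 and -0.003 and by -0.87, 0.42 and 0.30.

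With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split gave 0 genes past the adjusted threshold and the highest other split 8 (10 of 10 splits gave as many, which a real count of 0 fixes in advance, so this comparison says nothing about chance). At an unadjusted p under 0.05 it gave 505 against 1896 (8 of 10), and lists past the threshold 13 against 22 (7 of 10). The size of the small nucleolar RNA median was 0.36 against 0.33 (1 of 10). These RNAs were singled out after their values in the real split had been seen. The rank of that split is partly fixed by this choice and says little about chance. The split with 1896 genes set wildtype replicate 1 and knockout replicates 2 and 3 against the rest and called 0 genes at the adjusted threshold. A structure of the samples other than genotype was not tested. Neutrophil markers were high on these 3 arrays.

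Small nucleolar RNAs had lower means in knockout cells, and brightness, host transcript level and recovery of short RNA were tested as explanations. Lists matched on brightness reached no lower than -0.0795 in 10000 draws, which argues against brightness as the whole cause. The median of the genes that enclose them, over 31 RNAs with 1 measured host, was -0.0452 (95% interval -0.0711 to 0.00431). With each of the 27 genes counted once it was -0.021 (-0.0711 to 0.0206). These intervals come from resampling host genes, not samples. The values argue against a lower level of host transcripts as the whole cause for these 31 RNAs. Transcription itself was not measured, so lower host transcription stays open. A lower host transcript level also stays open for RNAs from non-coding hosts, whose list had a median of -0.27 (5 of 5 lower). Among these, Gas5 lay at -0.30 and its Snord47 at -0.46. A lower recovery of short RNAs may account for the pattern, since other short RNAs, among them Rny3, Rpph1 and 5S ribosomal RNA, had a median of -0.414, although Rn7sk lay at -0.02. No measure of that loss was used here, and a hypothesis of lower small nucleolar RNA in cells without AES stays open and is confounded with collection time.

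The low Y-linked genes on knockout replicates 1 and 3 could come from embryos with a pair of X chromosomes, from a lost sex chromosome or from exchanged labels. Xist was at most 5.66 on these 2 arrays, against 9.11 on wildtype replicate 1, which argues against cells with an inactive X. Wildtype replicates 1 and 2 had high Xist (9.11 and 7.41) along with high Y-linked genes (means 9.23 and 9.33). Sex-linked expression thus also varied among the wildtype arrays. The gap of at least 1.78 in Aes between the groups argues against an exchange between wildtype and knockout arrays. Loss of a sex chromosome stays open: the gap of at least 3.54 between the 3 Y-linked genes there and on the other arrays restates the pattern, and no genome data were used here.

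The shift of chromosome 12 genes could come from one region, from brightness, from genotype or from copy number. Of 10 segments along the chromosome, at least 9 lay on the side of the chromosome's median on each array (0.343 to 0.598 on knockout replicate 1, but -0.04 to 0.32 on knockout replicate 3), and the chromosome's median was at least 1.06 times the most extreme of 10000 lists matched on brightness on each array, which argue against one region and brightness as the whole cause. The lowest knockout median lay below the highest wildtype median (difference -0.367), which argues against genotype as the whole cause. Of the chromosome's genes, 93.7% were higher on knockout replicate 1 than on wildtype replicate 1, against 62.6% of other genes, but these arrays were picked by the shift, so the share restates it. A different number of copies in single leukaemias could not be tested on its own and stays open.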
